A study of Mus musculus with 10 samples.

How the data were processed

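The gene counts of the 10 libraries were made by the authors before deposit: per the submitters' processing notes, reads were aligned with STAR to GRCm38 and counted per gene, and DESeq2 was named for their own comparison, without versions. The deposited counts of 43432 gene identifiers were used as they were, and raw reads were not used here. Gene symbols, types, coordinates and lengths were taken from GENCODE M21 by Ensembl identifier. Of the identifiers 42548 were found there and 884 were left without a symbol.

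Per the sample labels, each library was made from sorted cells of 1 male mouse of 12 weeks, so replicates are separate animals. Per the series' design text, 4 replicates of each population were sorted, and 1 SI tuft and 1 SI epithelium library were discarded by the authors for quality. Cells were sorted into lysis buffer, messenger RNA was taken with poly(A) beads, and libraries were made with NuGEN Ovation V2 and Nextera XT kits, which mark no strand.

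Genes were kept by edgeR's filterByExpr (minimum count 10, total 15, smallest group 3), which left 19281 genes. Library sizes were scaled by TMM, with factors of 0.661 to 1.43. The edgeR quasi-likelihood test was fitted over all 10 libraries with a mean per group, and 3 comparisons were drawn from it. Each comparison was adjusted by the Benjamini-Hochberg method and a gene was called at an adjusted p (FDR) below 0.05. R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used.

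A fixed set of 34 gene lists was written before the data were examined, for tuft cell biology, epithelial lineages, thymic epithelium, contaminating cells and general states. Lists may share members. Each was tested with limma's camera on voom log2 CPM at a preset correlation of 0.01, with an estimated correlation, and with fry, and adjusted over the 34 lists. Camera called 21, 16 and 28 lists with the preset and 8, 7 and 13 with the estimated correlation for SI tuft against SI epithelium, thymic against SI tuft and thymic tuft against SI epithelium. The fry test called 22, 26 and 33. Members were also adjusted over the list alone.

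Genes were named by a rule set before the data were examined: 17 fixed genes, then for each comparison the 8 largest increases and 8 largest decreases. These had to be protein-coding, not ribosomal, with a usual symbol, a mean of at least 50 CPM in the higher group and libraries that did not overlap. For each list up to 2 members each way with at least 10 CPM were named, and for lists of contaminating cells the 2 most abundant members. Lck and Alas2, which were called below 10 CPM, and genes named for 1 comparison and then described in another, such as H2-Ab1, Gnb3, Acta2 and Dcn, were chosen after the values were seen. A pair of list members is counted within its lists but not reported here by itself.

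The alternatives fixed before the data were examined were DESeq2 size factors, upper quartile scaling, no filter, a filter of 10 CPM in 3 libraries, the DESeq2 Wald test, a fit of only 2 groups, the replicate number as a block, a minimum change of 2-fold, counts thinned to the smallest library, removal of the 50 most abundant genes and removal of each library. Subtraction of the partner library's share was added after seeing the data, as was a comparison of families with the same symbol stem.

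Cross-library shares were fitted by weighted least squares with no negative share, over 282 genes with at least 2000 counts in the thymic libraries and at most 2 counts over the SI tuft libraries. The reverse share was the median over 11 genes with at least 20000 counts in SI epithelium and less than 3% as many in SI tuft cells, and with counts in thymic library 4 below 0.02% of those in SI epithelium. Subtraction removed 0.320% to 0.423% of the counts of SI epithelium libraries and 1.07% to 1.48% of those of thymic libraries 1 to 3.

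The procedure was tried on simulated counts with the means of these libraries and a spread for each gene pooled over all groups. In these counts 100 well-expressed genes were changed 2-fold and 100 were changed 4-fold. In SI tuft against SI epithelium 11% and 65% of them were recovered over 18484 genes, with 3.80% of calls false. In thymic against SI tuft cells the values were 25%, 75% and 4.76% over 18623 genes, and in thymic tuft against SI epithelium 20%, 73% and 4.12% over 18646 genes. Spreads within groups differed (0.262 in SI epithelium, 0.489 in SI tuft and 0.781 in thymic tuft cells). Recovery with each group's own spread was not tested. In each comparison 10 of 10 simulated lists of 20 genes changed 2-fold were called over 19281 genes, and 0 of 10 unchanged lists were. Simulated genes were drawn independently, whereas estimated correlations within the real lists reached 0.812. The simulated lists therefore do not check camera at the preset correlation for such lists. Simulated cross-library shares over 282 genes were recovered with an error of at most 4.3%.

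The spread between replicates, as edgeR's biological coefficient of variation, was 0.262 in SI epithelium, 0.489 in SI tuft, 0.781 in thymic tuft cells and 0.613 over all groups. Correlations of log2 CPM were 0.885 to 0.993 within groups (n = 12 pairs) and 0.661 to 0.891 between groups (n = 33 pairs). No pair of libraries was a duplicate by its counts: chi-square per degree of freedom was 35.3 to 207 within groups. The 50 most abundant genes held 40.2 ± 1.83% (n = 3), 40.9 ± 4.56% (n = 3) and 16.3 ± 0.455% (n = 4) of the counts in SI epithelium, SI tuft and thymic tuft libraries.

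The overlap of comparisons that share the SI epithelium libraries was first simulated with 1 spread for all groups, and then with each group's own spread after that result was seen; both are given. The 3 epithelial libraries could not be divided into separate control sets of at least 2 libraries.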

Results

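RNA-seq was performed on tuft cells, rare chemosensory epithelial cells with an apical tuft of microvilli, sorted from the small intestine (SI) and the thymus of naive male mice. The mice were homozygous for Flare25, a fluorescent reporter allele of Il25, a cytokine gene used to identify tuft cells. Reporter-positive SI tuft cells (n = 3 libraries), reporter-positive thymic tuft cells (n = 4) and reporter-negative EPCAM-positive CD45-negative SI epithelial cells (n = 3) were compared. Each library came from 1 mouse, with 35000 to 36000 SI tuft cells, 1350 to 1900 thymic tuft cells or 52000 to 57000 SI epithelial cells. Intestinal cells were released with DTT and EDTA, whereas thymic cells were released by enzymes, so organ, dissociation and cell number differed together.

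Libraries held 38.7 to 73.6 × 1e6 gene counts, and 18889 to 23179 genes had a count. A total of 3 counts in a library corresponded to 0.0408 to 0.0776 counts per 1e6 counts (CPM). The 3 groups separated on the first principal component, which held 63.4% of the variance, and on the second, which held 13.6%. Mitochondrial genes took 21.0 ± 2.58% (SD, n = 3) of the counts in SI epithelium, 28.2 ± 4.86% (n = 3) in SI tuft cells and 5.22 ± 0.652% (n = 4) in thymic tuft cells. Gene levels below are mean CPM ± SD over these n = 3, n = 3 and n = 4 libraries, and adjusted p values of single genes are from edgeR.

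**Figure D1:**
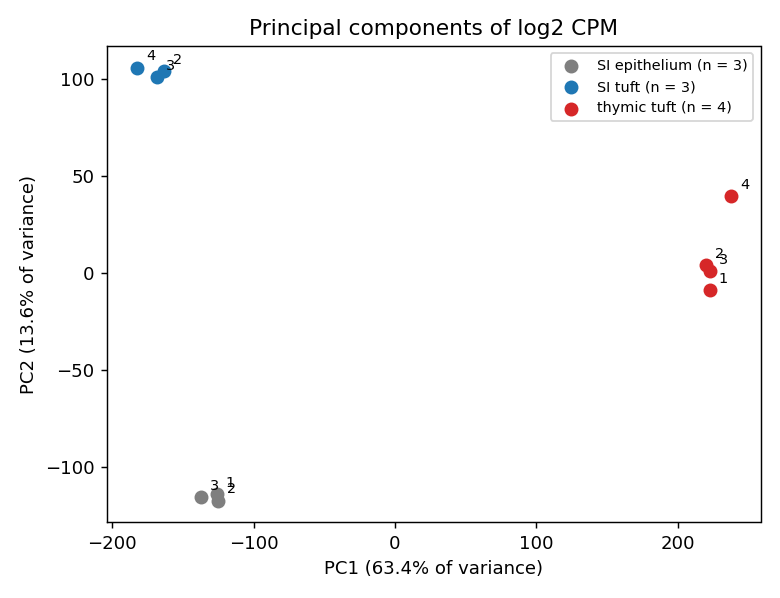
Each point is 1 library, placed on the first 2 principal components of log2 CPM (unitless axes, with the share of variance in %) and labelled with its replicate number. Thymic tuft libraries lie apart on the first component (63.4%), and SI tuft and SI epithelium libraries lie apart on the second (13.6%).

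The comparison of SI tuft cells with SI epithelium asked which genes distinguish tuft cells from the other epithelial cells of the same organ. Transcripts of the tuft cell programme were far more abundant in SI tuft cells, where 38 of 39 measured tuft cell markers rose (38 adjusted over the list alone), with a median log2 fold change of 6.13. The markers of the other secretory lineages fell: 9 of 10 for goblet cells, 10 of 10 for Paneth cells (camera adjusted p = 0.074 with an estimated correlation) and 17 of 19 for enteroendocrine cells. SI tuft cells also had more transcripts of haematopoietic-type signalling genes and interferon-stimulated genes, and fewer of proliferation genes. Among 19281 genes tested, 2101 were higher and 2199 were lower in SI tuft cells by edgeR's quasi-likelihood test. The libraries of both groups did not overlap for 51.1% of genes, against 10% by chance.

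Pou2f3, the transcription factor required for tuft cell development (ENSMUSG00000032015, GRCm38 chromosome 9, 43123939 to 43210369), rose from 13.0 ± 1.94 to 694 ± 104 CPM (log2 fold change 5.74, SE 0.20, adjusted p = 2.87e-09). Il25 itself (ENSMUSG00000040770, chromosome 14, 54932695 to 54935837) rose from 0.291 ± 0.158 to 26.7 ± 2.67 CPM (log2 fold change 6.49, SE 0.71, adjusted p = 3.65e-05). Trpm5, the cation channel of taste transduction (ENSMUSG00000009246, chromosome 7, 143069153 to 143094642), went from 45.1 ± 23.3 to 5266 ± 716 CPM (log2 fold change 6.87, SE 0.36, adjusted p = 5.84e-08). The tuft cell kinase gene Dclk1 (ENSMUSG00000027797, chromosome 3, 55242364 to 55539068) went from 27.5 ± 4.09 to 2574 ± 271 CPM (log2 fold change 6.55, SE 0.21, adjusted p = 2.81e-09). Avil, Gfi1b and Il17rb rose by 6.33, 6.03 and 6.00 log2 units. The 1 marker that did not pass the test was Gnb3, a G protein subunit gene, at 1.08 ± 0.222 CPM in epithelium and 2.42 ± 2.06 CPM in SI tuft cells (adjusted p = 0.278). After subtraction of counts shared with thymic libraries, a setting chosen after seeing the data, 39 of 39 markers were higher. Trpm5, Dclk1, Avil, Il17rb, Ptgs1, Il4ra, Col15a1, Dnah6 and Mmp7 each overlap another annotated gene, and the library kit marks no strand, so their counts are uncertain by what that neighbour adds. The same holds for Irf7, Lcp1, Krt5, Krt7, Plk1, Olfm4, Gata5, Cldn3, Hoxa3, Cd274, Cd3e, Lck and Alas2 below. Epcam, whose product was used in the epithelial gate, was at 1283 ± 88.7 and 1599 ± 92.5 CPM (adjusted p = 0.13).

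Nrgn, Col15a1, Folr1, Dnah6, Rgs13, Ly6g6f, Car7 and Trpm5 were the 8 genes with the largest increases by the fixed rule, at log2 fold changes of 6.87 to 7.23. In SI epithelium library 3, Nrgn, Col15a1 and Dnah6 were at 9.90, 7.92 and 3.17 CPM, against 0.552 to 2.24 CPM in libraries 1 and 2. Trpm5 was also highest there (71.9 against 30.5 and 32.8 CPM), whereas Rgs13 and Car7 were not set apart. The folds and order of these genes are limited by that library. Nrgn, which encodes the calmodulin-binding protein neurogranin, rose from 4.68 ± 4.52 to 708 ± 59.5 CPM (log2 fold change 7.23, SE 0.64, adjusted p = 6.41e-06). Car7, a carbonic anhydrase gene, rose from 1.30 ± 0.228 to 157 ± 57.3 CPM (log2 fold change 6.91, SE 0.31, adjusted p = 1.77e-08). The 8 largest decreases were in Mptx2, Defa29, AY761184, Zg16, Nts, Mmp7, Defa30 and Fer1l6, at -5.56 to -7.35. Mmp7, the Paneth cell protease that activates defensins, fell from 284 ± 24.0 to 5.45 ± 2.88 CPM (log2 fold change -5.70, SE 0.55, adjusted p = 1.37e-05). Nts, which encodes the gut hormone neurotensin, fell from 56.0 ± 8.85 to 1.06 ± 0.193 CPM (log2 fold change -5.71, SE 0.41, adjusted p = 1.02e-06). Defa29, Defa30 and AY761184 belong to the near-identical defensin family, so the split of counts among its members is uncertain.

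Among genes for chemosensing and lipid mediators, 6 of 15 members of the taste signalling cascade rose (6 adjusted over the list alone, camera adjusted p = 0.106 with an estimated correlation), among them the phospholipase gene Plcb2, by 6.04 (SE 0.28, adjusted p = 2.05e-08) on the log2 scale. With the counts shared with thymic libraries subtracted, 8 of the 15 rose. None of the 29 measured bitter taste receptors rose by edgeR, and 2 fell (0 adjusted over the list alone). After subtraction of counts shared with thymic libraries, a setting chosen after seeing the data, 2 rose and 0 fell, with Tas2r138 at adjusted p = 0.0299 (range over alternatives 0.0299 to 0.984). Of 19 metabolite and nucleotide receptors, 4 rose and 5 fell (4 and 7 adjusted over the list alone, 4 and 3 after the same subtraction). Ffar3, a short-chain fatty acid receptor gene, rose from 6.69 ± 1.71 to 682 ± 46.1 CPM (log2 fold change 6.67, SE 0.58, adjusted p = 5.31e-06). The succinate receptor gene Sucnr1 (ENSMUSG00000027762, chromosome 3, 60081869 to 60087566) rose from 0.609 ± 0.337 to 26.1 ± 4.83 CPM (log2 fold change 5.42, SE 0.68, adjusted p = 0.000111). Of 21 eicosanoid synthesis genes 7 rose and 3 fell (7 and 4 adjusted over the list alone, camera adjusted p = 0.074 with an estimated correlation). After the same subtraction 7 rose and 1 fell. Alox5, the first enzyme of leukotriene synthesis, rose from 9.77 ± 2.68 to 1062 ± 85.8 CPM (log2 fold change 6.76, SE 0.28, adjusted p = 1.10e-08). Ptgs1, the constitutive cyclooxygenase gene, rose from 12.1 ± 0.570 to 849.7 ± 125 CPM (log2 fold change 6.13, SE 0.18, adjusted p = 2.81e-09). The leukotriene C4 synthase gene Ltc4s and the prostaglandin D synthase gene Hpgds rose by 6.09 and 4.97 log2 units. An antisense gene overlaps Ltc4s, whose counts are uncertain to that extent.

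In the type 2 cytokine circuit, 8 of 16 genes rose and 2 fell (9 and 2 adjusted over the list alone). After subtraction of counts shared with thymic libraries 8 rose and 1 fell. Il4ra and Il13ra1, which encode the subunits of the IL-13 receptor, rose from 39.5 ± 8.11 to 91.7 ± 1.46 CPM (log2 fold change 1.21, SE 0.19, adjusted p = 0.000675) and from 45.6 ± 6.09 to 84.0 ± 9.45 CPM (log2 fold change 0.88, SE 0.18, adjusted p = 0.0036). Il33 fell from 19.7 ± 3.81 to 6.06 ± 2.21 CPM. Chat, the acetylcholine-synthesising enzyme, rose from 4.10 ± 0.577 to 336 ± 66.0 CPM (log2 fold change 6.35, SE 0.31, adjusted p = 3.08e-08). Of all 16 cholinergic and neuronal genes 2 rose and 4 fell (2 and 4 adjusted over the list alone, 2 and 2 after subtraction). Snap25, a gene of vesicle release, was among the latter (166 ± 22.8 to 16.8 ± 3.32 CPM). Of 20 genes of haematopoietic-type signalling 14 rose and 2 fell (14 and 2 adjusted over the list alone). The kinase gene Matk rose from 21.4 ± 5.10 to 2333 ± 302 CPM (log2 fold change 6.76, SE 0.29, adjusted p = 1.37e-08) and Ptprc, which encodes CD45, from 6.62 ± 3.69 to 161 ± 22.2 CPM (log2 fold change 4.61, SE 0.42, adjusted p = 7.38e-06). The kinase gene Syk and the actin-bundling gene Lcp1 fell by 1.69 and 1.67 on the log2 scale. Markers of T cells, B cells, and myeloid and dendritic cells each had 1 member that rose, of 18, 7 and 12 (1 each adjusted over the list alone), and the 5 red blood cell genes had no call by edgeR in either direction (0 adjusted over the list alone). Cd3e, a T cell receptor complex gene, was at 1.80 ± 1.07 and 11.7 ± 3.79 CPM (adjusted p = 0.0587), and Lck, the T cell kinase that was called, at 0.435 ± 0.0331 and 9.40 ± 3.73 CPM (adjusted p = 0.0101).

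Interferon-stimulated genes rose in 13 of 20 cases with none lower by edgeR (15 and 0 adjusted over the list alone), led by Isg15, from 12.5 ± 2.36 to 90.0 ± 18.4 CPM (log2 fold change 2.85, SE 0.24, adjusted p = 4.22e-06), and Irf7, from 81.5 ± 6.62 to 501 ± 46.9 CPM (log2 fold change 2.62, SE 0.15, adjusted p = 1.71e-07). Of 17 genes of MHC class I presentation 8 rose and 3 fell (10 and 3 adjusted over the list alone, camera adjusted p = 0.106 with an estimated correlation). The class I gene H2-D1 went from 339 ± 61.2 to 1771 ± 169 CPM. Actin bundle and brush border genes rose in 7 of 14 cases and fell in 1 (8 and 2 adjusted over the list alone), and the bundling gene Espn rose to 691 ± 94.9 CPM (log2 fold change 3.94, SE 0.18, adjusted p = 2.16e-08). The keratin gene Krt18 went from 865 ± 119 to 15030.0 ± 836 CPM, and Krt7 from 190.4 ± 28.0 to 19.3 ± 1.66 CPM. Proliferation genes fell in 18 of 24 cases (20 adjusted over the list alone), for example the mitotic kinase Plk1, from 102 ± 11.2 to 19.3 ± 1.34 CPM. Of 14 intestinal stem cell genes 9 fell and 1 rose (10 and 1 adjusted over the list alone, camera adjusted p = 0.101 with an estimated correlation): Olfm4 fell from 638 ± 102 to 89.2 ± 25.5 CPM and Sox9 rose from 126 ± 14.5 to 673 ± 37.8 CPM.

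Goblet cell markers fell in 9 of 10 cases and Paneth cell markers in 10 of 10 (9 and 10 adjusted over the list alone). The set test gave adjusted p = 0.028 with an estimated correlation for goblet cells and adjusted p = 0.074 with an estimated correlation for Paneth cells. Zg16, a goblet cell lectin gene, fell from 26960.0 ± 1606 to 498 ± 69.9 CPM (log2 fold change -5.76, SE 1.17, adjusted p = 0.00374). The Zg16 call ended under 1 setting (adjusted p = 0.0826, over a range of 7.88e-09 to 0.0826), as did that of Defa30 (0.0734, over 5.3e-06 to 0.0734). Their spread was estimated over all groups, and Zg16 was at 167 to 260 CPM in thymic libraries 1 to 3 and 1.31 CPM in library 4. The SE and adjusted p of Zg16 therefore do not measure the spread of the SI libraries alone, which were at 25780 to 28790 and 422 to 559 CPM. The 17 enteroendocrine genes that fell (19 adjusted over the list alone) included Gip, from 543 ± 81.8 to 22.1 ± 13.4 CPM. Enterocyte markers did not fall: 3 of 23 rose (3 adjusted over the list alone, camera adjusted p = 0.0763 with an estimated correlation), with a median log2 fold change of 0.62. The fatty acid binding protein gene Fabp1 went from 1278 ± 247 to 6077 ± 823 CPM (log2 fold change 2.25, SE 0.46, adjusted p = 0.00414). Immediate early and heat shock genes fell in 10 of 17 cases (12 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.074 with an estimated correlation), Nr4a1 among them (191 ± 35.3 to 34.1 ± 9.29 CPM). Of 76 nuclear oxidative phosphorylation genes 13 rose (13 adjusted over the list alone, adjusted p = 0.337 with an estimated correlation). Of 8 mitochondrial messenger RNAs 6 rose (7 adjusted over the list alone, adjusted p = 0.186 with an estimated correlation), and the mitochondrial shares were 28.2% in SI tuft cells and 21.0% in epithelium. Cytoplasmic ribosomal protein genes fell in 15 of 76 cases and rose in 1, Rpl26 (15 and 1 adjusted over the list alone, adjusted p = 0.245 with an estimated correlation). The Rpl26 call ended under 8 settings, among them removal of any 1 SI library (adjusted p = 0.0568 to 0.152, over a range of 0.00269 to 0.161).

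Lists of thymic genes were also called lower in SI tuft cells than in SI epithelium. Of medullary thymic epithelium genes 8 of 13 fell and 1 rose, Cldn3 (adjusted p = 0.106 with an estimated correlation). The Cldn3 call ended under 9 settings, among them removal of any 1 SI library (adjusted p = 0.078 to 0.132, over a range of 0.000843 to 0.132). Of thymic patterning factors 7 of 9 fell and 1 rose, Hoxa3 (adjusted p = 0.194 with an estimated correlation), and 9 of 18 MHC class II genes fell and 1 rose, Cd274 (adjusted p = 0.287 with an estimated correlation). Keratins fell in 15 of 38 cases and rose in 4, and 3 of 10 genes fell in each of the cortical and cornified thymic epithelium lists. Adjusted over the list alone, the lower counts were 8, 7, 10, 15, 3 and 3, with 3 cornified genes and 5 keratins higher. SI epithelium libraries 1, 2 and 3 held counts of 282 thymus-restricted genes in the proportions of thymic tuft libraries 3, 2 and 1, at 0.501%, 0.542% and 0.559% of those libraries' counts. After the estimated share was subtracted, a setting chosen after seeing the data, 1 medullary gene, 0 thymic patterning factors, 1 MHC class II gene, 7 keratins, 1 cortical gene and 0 cornified genes were lower by edgeR. The medians of the medullary, patterning and class II lists were then above 0 (0.50, 1.70 and 0.33). Subtraction left 2124 genes higher and 1792 lower, with 412 of the 2199 lower calls lost. Of 29 measured Hox genes 6 rose and 1 fell (6 and 1 adjusted over the list alone), of 18 intestinal patterning factors 2 rose and 3 fell (2 and 3), and of 13 fibroblast and endothelium genes 2 fell (2). After subtraction 6 Hox genes were higher and 0 lower, 1 patterning factor was higher and 4 lower, and 1 fibroblast or endothelium gene was lower.

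The camera set test called 21 of the 34 lists with its preset correlation and 8 with an estimated one. For the cortical list the median and mean of 0.09 and 0.10 were above 0 while the test pointed down. When only SI tuft and SI epithelium entered the fit, 3475 genes were higher and 3513 lower. The number of lower genes was 1426 without SI epithelium library 1 and 1432 without library 2.

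**Figure D2:**
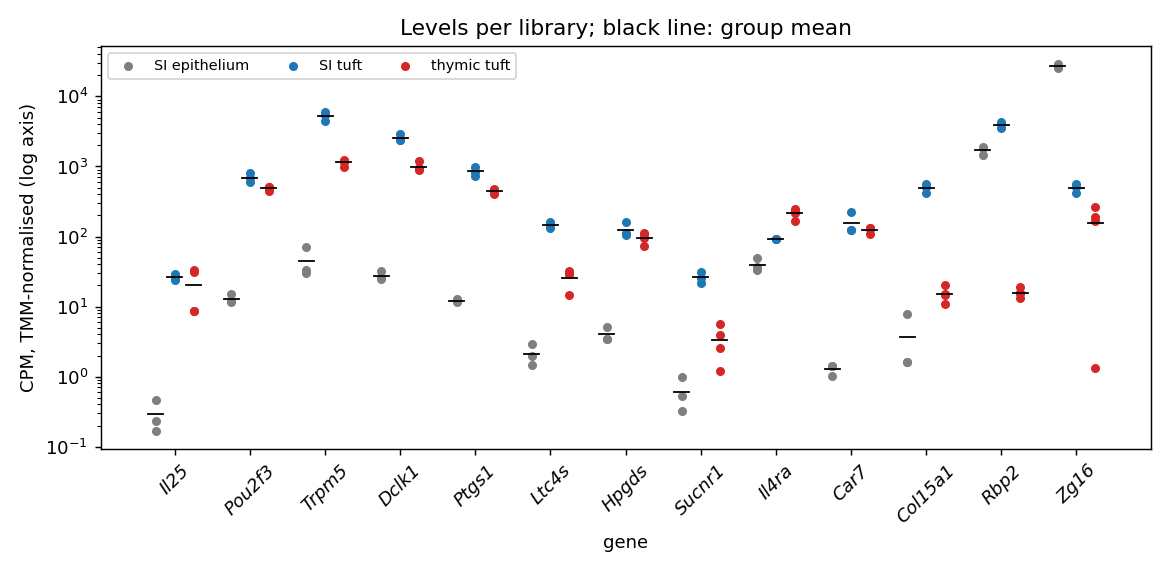
Levels of 13 genes in each library (CPM, normalised, log axis), with points coloured by group and a black line at the group mean. Pou2f3 means were 13.0, 694 and 492 CPM in SI epithelium, SI tuft and thymic tuft cells, and Il4ra was higher in thymic tuft cells than in either SI group.

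The comparison of thymic with SI tuft cells asked how tuft cells of both organs differ. Most tuft cell markers were at lower levels in thymic tuft cells: 30 of 39 were lower than in SI tuft cells, 4 were higher and 5 did not pass the test (30 and 4 adjusted over the list alone), with a median log2 fold change of -1.43. The set test gave adjusted p = 0.0533 with an estimated correlation. Bitter taste receptors, MHC class II genes, keratins, and patterning and medullary genes of the thymic epithelium were higher in thymic tuft cells, and enterocyte and brush border genes were lower. In total 5492 genes were higher and 4453 lower by edgeR. Libraries of the groups did not overlap for 51.2% of genes, against 5.71% by chance.

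Pou2f3 was at 492 ± 31.5 CPM in thymic tuft cells, below SI tuft cells (log2 fold change -0.50, SE 0.15, adjusted p = 0.0148). That call ended under 4 settings, with the thymic change at adjusted p = 0.0774 without SI tuft library 3 and 0.180 with DESeq2 size factors, over a range of 0.0117 to 0.180. Il25 was at 20.5 ± 13.7 CPM (log2 fold change -0.38, SE 0.51, adjusted p = 0.562). Trpm5 fell to 1148 ± 108 CPM (log2 fold change -2.20, SE 0.26, adjusted p = 2.34e-05) and Dclk1 to 989 ± 147 CPM (log2 fold change -1.38, SE 0.16, adjusted p = 1.49e-05). Avil, Gfi1b, Chat and Il17rb fell by 1.51, 1.96, 1.38 and 1.64 on the log2 scale. Larger differences were seen in the inhibitory sialic acid receptor gene Siglecf, at 1121 ± 56.7 and 18.0 ± 3.98 CPM (log2 fold change -5.96, SE 0.24, adjusted p = 5.66e-09). Matk was at 62.8 ± 15.3 CPM in thymic tuft cells (log2 fold change -5.21, SE 0.24, adjusted p = 1.53e-08). Gnb3 rose from 2.42 ± 2.06 to 189.5 ± 17.4 CPM (log2 fold change 6.29, SE 0.81, adjusted p = 4.6e-05) and Nrep from 5.54 ± 0.982 to 172 ± 36.6 CPM (log2 fold change 4.96, SE 0.30, adjusted p = 9.36e-08). Epcam and Ptprc were lower, by -1.11 and -1.38.

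All 29 measured bitter taste receptors were higher in thymic tuft cells (29 adjusted over the list alone), with a median log2 fold change of 9.04, or 6.71 with the 19 receptors that had no count in SI tuft cells set at their bound. Of 35 receptors listed, 29 passed the filter on counts. Those 19 passed it through their thymic counts, so the number called higher was largely fixed by the filter. Tas2r138 rose from 0.0758 ± 0.0731 to 30.7 ± 6.25 CPM (log2 fold change 8.59, SE 0.72, adjusted p = 1.16e-06), although reads of such similar receptors are assigned with less certainty. Of 15 taste cascade genes 8 rose and 5 fell (8 and 5 adjusted over the list alone), with Rgs21, a regulator of G protein signalling, rising from 0.206 ± 0.179 to 41.1 ± 14.1 CPM. Sucnr1 fell to 3.32 ± 1.89 CPM (log2 fold change -2.97, SE 0.54, adjusted p = 0.000649) and Ffar3 to 7.16 ± 4.52 CPM (log2 fold change -6.57, SE 0.51, adjusted p = 5.99e-07), whereas Hcar2, a receptor for niacin and ketone bodies, rose from 0.114 ± 0.176 to 28.3 ± 2.79 CPM. Over the 19 metabolite and nucleotide receptors, 4 rose and 9 fell (5 and 10 adjusted over the list alone). Among eicosanoid synthesis genes 8 rose and 8 fell of 21 (8 and 8 adjusted over the list alone): Alox5, Ptgs1 and Ltc4s fell to 393 ± 84.2, 451 ± 34.1 and 26.0 ± 7.81 CPM, and Hpgds was at 96.5 ± 17.2 CPM (log2 fold change -0.38, adjusted p = 0.172).

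Type 2 cytokine circuit genes rose in 5 and fell in 5 of 16 cases (5 and 5 adjusted over the list alone). Il13 had 3 counts over the SI tuft libraries and 224 ± 54.4 CPM in thymic tuft cells, a ratio of 8641 with a counting interval of 2957 to 41900. Il4ra (ENSMUSG00000030748, chromosome 7, 125552120 to 125579474) rose to 214 ± 35.3 CPM (log2 fold change 1.23, SE 0.18, adjusted p = 0.000154), and Il13ra1 was at 84.8 ± 9.29 CPM (log2 fold change 0.01, SE 0.17, adjusted p = 0.948). Il18 fell from 27.8 ± 2.19 to 0.236 ± 0.158 CPM (log2 fold change -6.88, SE 0.49, adjusted p = 3.19e-07). Cholinergic and neuronal genes rose in 7 and fell in 3 of 16 cases (7 and 3 adjusted over the list alone). Of haematopoietic-type signalling genes 12 of 20 fell and 4 rose (12 and 4 adjusted over the list alone, camera adjusted p = 0.0514 with an estimated correlation). Was, which encodes an actin regulator of blood cells, fell from 17.8 ± 2.40 to 0.0486 ± 0.0220 CPM, and Lcp1 rose to 711 ± 81.4 CPM (log2 fold change 6.00, SE 0.25, adjusted p = 7.14e-09).

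MHC class II presentation genes were higher in 17 of 18 cases (17 adjusted over the list alone), with a median log2 fold change of 7.17. Markers of myeloid and dendritic cells and of B cells, which also express class II genes, rose in 8 of 12 and 3 of 7 cases. H2-Ab1, a class II chain, rose from 11.9 ± 9.17 to 1803 ± 230.2 CPM (log2 fold change 7.24, SE 0.57, adjusted p = 6.99e-07), and Cd80, a costimulatory ligand with no count in SI tuft cells, was at least 2728-fold higher at 70.7 ± 9.95 CPM. MHC class I genes rose in 7 and fell in 4 of 17 cases, and interferon-stimulated genes rose in 7 and fell in 7 of 20 (7 and 4, and 7 and 7, adjusted over the list alone). Thymic patterning factors were higher in 8 of 9 cases and Hoxa3 was lower (8 and 1 adjusted over the list alone). Foxn1, the master regulator of thymic epithelium, had 1 count over the SI tuft libraries and 169 ± 30.0 CPM in thymic tuft cells, a ratio of 19580 (counting interval 3515 to 773500). Medullary thymic epithelium genes rose in 12 of 13 cases and Cldn3 fell (12 and 1 adjusted over the list alone), at a median of 11.06, or 10.38 at the bound. Cornified thymic epithelium genes rose in 10 of 10 cases (10 adjusted over the list alone, camera adjusted p = 0.0735 with an estimated correlation), and 6 of 10 cortical genes rose while 2 fell (6 and 2). Keratins rose in 26 of 38 cases and fell in 5 (27 and 5 adjusted over the list alone), at a median of 7.43, or 6.21 at the bound. Krt14 was at least 3021-fold higher at 78.3 ± 16.3 CPM, and Krt18 fell to 1308 ± 216 CPM (log2 fold change -3.52, SE 0.16, adjusted p = 1.58e-08).

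Krtdap, Alox12e, Serpinb2, Krt77, Spink5, Irf4, Dgkk and Csn2 were the 8 genes with the largest fitted increases by the fixed rule. All but Spink5 and Csn2 had no count in SI tuft cells, so their order is not determined: the floors of Irf4 and Dgkk were 3777-fold and 3684-fold, below the ratios of Rgs5 (29020), Foxn1 (19580) and Il13 (8641). Krtdap, a keratinocyte differentiation gene (ENSMUSG00000074199, chromosome 7, 30787896 to 30791097), had no count in SI tuft cells and 306 ± 48.7 CPM in thymic tuft cells, at least 11800-fold higher (adjusted p = 9.44e-09). Irf4, a lymphocyte transcription factor (ENSMUSG00000021356, chromosome 13, 30749226 to 30766976), was at least 3777-fold higher at 97.9 ± 5.62 CPM (adjusted p = 1.02e-07). Csn2, which encodes the milk protein beta-casein (ENSMUSG00000063157, chromosome 5, 87692624 to 87699630), had 1 SI tuft count and 414 ± 60.6 CPM in thymic tuft cells, a ratio of 47920 (counting interval 8601 to 1893000). Floors are 3 counts over a group, and intervals and floors cover counting error only. The 8 largest decreases were in Cyp2b10, Mlip, Smpx, Cyp2c66, Rbp2, Cyp2c29, Alpi and Cgref1, at log2 fold changes of -7.85 to -8.11. Cyp2b10, Cyp2c66, Cyp2c29, Alpi and Cgref1 were far lower in thymic library 4 than in libraries 1 to 3, which hold counts shared with SI epithelium, so their folds and order are limited by these counts. Rbp2, the intestinal retinol-binding protein, fell from 3955 ± 407 to 15.8 ± 2.32 CPM (log2 fold change -7.96, SE 0.20, adjusted p = 6.24e-10). Cyp2c66 and Cyp2c29 have near-identical relatives, and Serpinb2 and Cyp2c29 overlap another annotated gene, so their counts are uncertain.

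Intestinal identity genes were lower in thymic tuft cells. Enterocyte markers fell in 23 of 23 cases (23 adjusted over the list alone), at a median of -6.19. Intestinal patterning factors fell in 14 of 18 cases and rose in 2, Foxa1 among them (14 and 3 adjusted over the list alone, camera adjusted p = 0.0557 with an estimated correlation). Gata5 went from 193 ± 5.50 to 1.54 ± 0.379 CPM (log2 fold change -6.96, SE 0.22, adjusted p = 1.88e-09). The Foxa1 call ended without SI tuft library 3 or 4 (adjusted p = 0.0777 and 0.0829, over a range of 0.00203 to 0.0829). Of 29 Hox genes 10 rose and 5 fell (10 and 5 adjusted over the list alone). Actin bundle and brush border genes fell in 12 of 14 cases (12 adjusted over the list alone), and the bundling gene Fscn1 rose. Intestinal stem cell genes fell in 5 and rose in 3 of 14 cases (5 and 3 adjusted over the list alone), with Lgr5 falling from 60.8 ± 3.23 to 2.54 ± 0.622 CPM. Proliferation genes fell in 21 of 24 cases (21 adjusted over the list alone, camera adjusted p = 0.0735 with an estimated correlation). Enteroendocrine genes rose in 4 and fell in 8 of 19 cases (5 and 8 adjusted over the list alone).

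Goblet cell markers fell in 5 and rose in 1, Fcgbp, of 10 cases, and Paneth cell markers fell in 1 and rose in 1 of 10, Itln1 and Mmp7 (the same numbers adjusted over the list alone). Thymic tuft libraries 1, 2 and 3 held 11 abundant intestinal epithelial transcripts at a median of 0.860%, 0.959% and 0.918% of the counts in SI epithelium libraries 3, 2 and 1, and library 4 at 0.0110%, a library on which these genes were selected. After subtraction of the estimated share, 6 goblet and 5 Paneth markers fell and 1 of each rose.

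Markers of other cell types were compared as well. Fibroblast and endothelium genes rose in 11 of 13 cases (11 adjusted over the list alone, camera adjusted p = 0.0982 with an estimated correlation). The pericyte gene Rgs5 was at 752 ± 257 CPM against 3 counts over the SI tuft libraries, a ratio of 29020 (counting interval 9930 to 140700). The matrix gene Dcn was at 37.0 ± 35.5 CPM. Myeloid and dendritic cell genes rose in 8 and fell in 1 of 12 cases (9 and 1 adjusted over the list alone), B cell genes rose in 3 of 7 (3) and T cell and thymocyte genes rose in 5 and fell in 2 of 18 (5 and 2). Camera called none of these 3 lists, with adjusted p = 0.0651, 0.0954 and 0.465 at the preset correlation. The fry test called the myeloid and B cell lists, with adjusted p = 0.00017, 0.000315 and 0.189 in the same order. Lyz2, a macrophage lysozyme gene, rose from 8.07 ± 5.64 to 183 ± 19.0 CPM, Cd79b from 2.56 ± 0.996 to 25.1 ± 8.61 CPM and Tcf7 from 5.85 ± 1.93 to 46.4 ± 24.1 CPM. Of 5 red blood cell genes 1 rose, Alas2 (0.0443 ± 0.0548 to 2.87 ± 1.13 CPM), and 2 fell (1 and 4 adjusted over the list alone). Immediate early and heat shock genes rose in 7 and fell in 3 of 17 cases (7 and 3 adjusted over the list alone). Mitochondrial messenger RNAs fell in 8 of 8 cases (8 adjusted over the list alone, camera adjusted p = 0.0916 with an estimated correlation). Nuclear oxidative phosphorylation genes fell in 68 of 76 (70 adjusted over the list alone, adjusted p = 0.0909 with an estimated correlation) and ribosomal protein genes in 40 of 76, with 1 higher (40 and 2 adjusted over the list alone, adjusted p = 0.311 with an estimated correlation). The mitochondrial share was 5.22% in thymic and 28.2% in SI tuft libraries.

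The set test called 16 of 34 lists with the preset and 7 with an estimated correlation. Median, mean and test differed in sign for 5 lists: metabolite receptors (-1.89, 0.09, down), eicosanoid synthesis (-0.04, 1.78, down), type 2 circuit (-0.16, 0.77, down), interferon-stimulated genes (0.11, 0.37, down) and Paneth cells (0.21, 0.01, down). Organ, dissociation and the number of sorted cells differ together between these groups, and their effects on a gene cannot be separated. With genes held to at least 10 CPM in 3 libraries, so that fewer were tested, 3289 genes were higher.

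**Figure D3:**
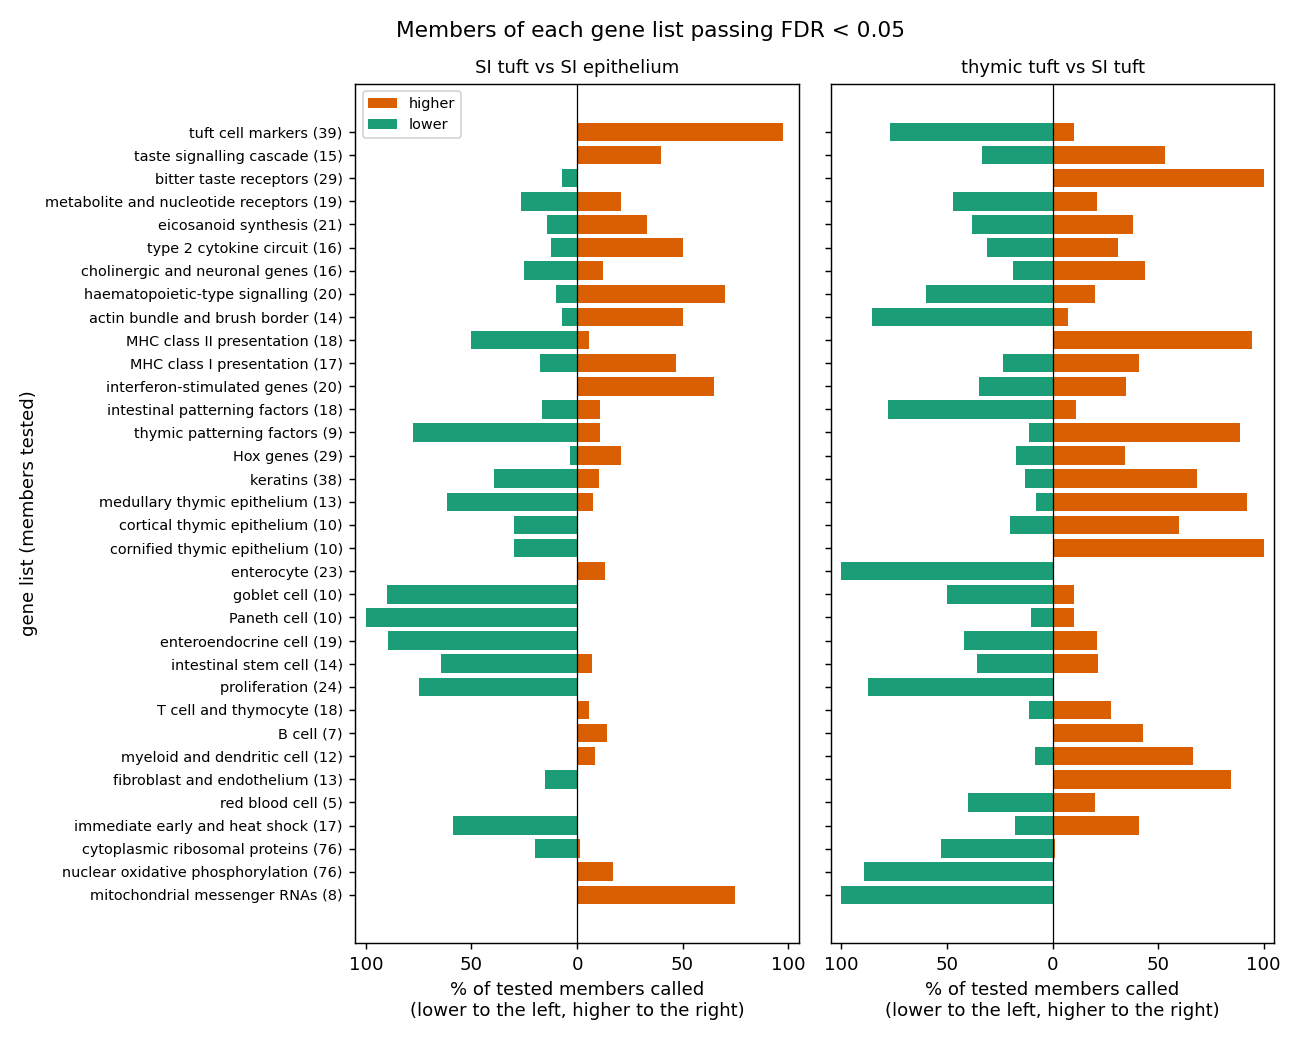
Share of the tested members of each of 34 gene lists (in %, members tested in brackets) called higher (orange, to the right) or lower (green, to the left) at FDR < 0.05 in each comparison. Tuft cell markers were higher in SI tuft cells than in epithelium in 38 of 39 cases and lower in thymic than SI tuft cells in 30 of 39.

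Thymic tuft cells were set against SI epithelium to ask which part of the tuft cell programme is shared by both organs. All 39 tuft cell markers rose in thymic tuft cells against SI epithelium (39 adjusted over the list alone), at a median log2 fold change of 4.76. Of the 2101 genes higher in SI tuft cells than in epithelium, 1203 (57.3%) were also higher in thymic tuft cells than in epithelium. Of the same 2101 genes 298 were lower in thymic tuft cells than in epithelium. Against SI tuft cells, 1108 of the 2101 (52.7%) were lower in thymic tuft cells, 330 (15.7%) were higher and 663 (31.6%) were not called, and of the 1108 genes 303 were still above epithelium. Over all 19281 genes, 4453 were lower and 5492 higher in that comparison. The 2101 genes were selected as high in the same SI tuft libraries, which favours lower values in thymic tuft cells. How far this selection accounts for the 1108 genes was not tested. In total 5514 genes were higher and 4297 lower in thymic tuft cells than in SI epithelium by edgeR, with no overlap between the libraries for 55.5% of genes against 5.71% by chance.

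Pou2f3 was higher than in epithelium (log2 fold change 5.24, SE 0.19, adjusted p = 2.22e-09), as were Il25 (6.11, SE 0.69, adjusted p = 1.49e-05), Trpm5 (4.67, SE 0.32, adjusted p = 2.19e-07), Dclk1 (5.17, SE 0.20, adjusted p = 3.06e-09) and Ptgs1 (5.21, SE 0.17, adjusted p = 1.98e-09). Sucnr1 rose by 2.45 and Il4ra by 2.44 log2 units. Gnat3, the taste G protein gustducin, rose from 3.97 ± 1.05 to 586 ± 152 CPM (log2 fold change 7.21, SE 0.45, adjusted p = 1.31e-07). Pax9, Axl, Ankrd33b, Ccr4, Prrg3, Hdac9, Klk7 and Saa3 had the 8 largest increases, at 7.72 to 7.96. Their low epithelial levels are close to the share of thymic counts in the epithelial libraries, so these folds and their order are limited by the shared counts. Pax9, a pharyngeal pouch transcription factor that overlaps Slc25a21, rose from 0.205 ± 0.128 to 50.5 ± 8.10 CPM (log2 fold change 7.96, SE 0.66, adjusted p = 1.14e-06). Afp, Cyp2c29, Zg16, AY761184, Tff3, Cyp2b10, Enpp7 and Defa30 had the 8 largest decreases, at -7.30 to -7.47. Their thymic levels were lower in library 4 than in libraries 1 to 3, which hold counts shared with SI epithelium, so these folds and their order are limited as well.

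Against epithelium, 11 of 15 taste cascade genes rose and 2 fell (adjusted p = 0.0551 with an estimated correlation), 29 of 29 bitter receptors rose, and 14 of 21 eicosanoid genes rose while 4 fell (adjusted p = 0.0522 with an estimated correlation). The number of bitter receptors was largely fixed by the filter on counts, which most of them passed through thymic libraries. Type 2 circuit genes rose in 11 of 16 cases and fell in 3 (12 and 4 adjusted over the list alone, adjusted p = 0.0565 with an estimated correlation). Haematopoietic-type signalling genes rose in 16 of 20 cases (17 adjusted over the list alone), MHC class II genes in 17 of 18, interferon-stimulated genes in 17 of 20, and thymic patterning factors in 8 of 9 (9 adjusted over the list alone). Medullary genes rose in 11 of 13 cases and fell in 1, with the basal keratin Krt5 going from 3.26 ± 0.605 to 636 ± 54.8 CPM (log2 fold change 7.61, SE 0.47, adjusted p = 1.09e-07). After subtraction the medians of the thymic patterning and medullary lists went from 7.45 and 7.47 to 12.19 and 12.05, so folds such as that of Krt5 are limited by the shared counts as well. Enterocyte markers fell in 22 of 23 cases, intestinal patterning factors fell in 14 of 18 and rose in 1, and proliferation genes fell in 24 of 24. Goblet cell markers fell in 9 of 10 cases (adjusted p = 0.0501 with an estimated correlation), Paneth cell markers in 10 of 10 (adjusted p = 0.0912 with an estimated correlation), and enteroendocrine genes in 16 of 19, with 1 higher. For lists given no other number, counts adjusted over the list alone were the same.

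Markers of contaminating cells were also compared between thymic tuft cells and SI epithelium. Myeloid and dendritic cell genes rose in 9 of 12 cases (9 adjusted over the list alone, adjusted p = 0.0522 with an estimated correlation). Fibroblast and endothelium genes rose in 11 of 13 (12 adjusted over the list alone, adjusted p = 0.0705 with an estimated correlation). Of T cell and thymocyte genes 9 of 18 rose and 1 fell, of B cell genes 4 of 7 rose, and of red blood cell genes 1 of 5 rose and 1 fell (the same numbers adjusted over the list alone). Camera called none of these 3 lists, with adjusted p = 0.0825, 0.075 and 0.954 at the preset correlation. The fry test called the T cell and B cell lists, with adjusted p = 0.00675, 0.00016 and 0.951 in the same order. Acta2, a smooth muscle actin gene, rose from 0.188 ± 0.116 to 27.4 ± 17.1 CPM. Mitochondrial messenger RNAs fell in 8 of 8 cases (8 adjusted over the list alone, adjusted p = 0.1 with an estimated correlation), and the mitochondrial share was 5.22% against 21.0% in SI epithelium. With genes held to at least 10 CPM in 3 libraries, so that fewer were tested, 3536 genes were higher than in SI epithelium. The set test called 28 of 34 lists with the preset and 13 with an estimated correlation.

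Since both comparisons used the same 3 epithelial libraries, overlaps were set against simulated unchanged groups. In 20 simulations no gene was called higher in both comparisons. Unchanged groups give almost no calls by design, so this is no baseline for the 1203 genes observed. Independent lists of the observed sizes would share 601. For genes lower in both comparisons, 896 were observed against 490.1 for independent lists. The covariance of the log2 fold changes was 0.282, against 0.106 simulated with each group's own spread and 0.321 with 1 spread for all groups, and the correlation across genes was 0.0437 against 0.215 and 0.533. The sign of the difference in covariance depended on the spread assumed. A single spread gave SI epithelium, the shared group, the pooled spread (0.613 over all groups against its own 0.262). With each group's own spread the highest simulated covariance was 0.116, which argues against the shared libraries alone as its source. That setting was chosen after the first result was seen, and the correlation was below both simulated values, so no size of a shared effect is claimed. After subtraction 1310 genes were higher in both comparisons, 1002 SI tuft genes were lower in thymic tuft cells and 435 were higher, the last of these being 584 with the DESeq2 Wald test. With a minimum change of 2-fold the last 2 counts were 702 and 206.

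**Figure D4:**
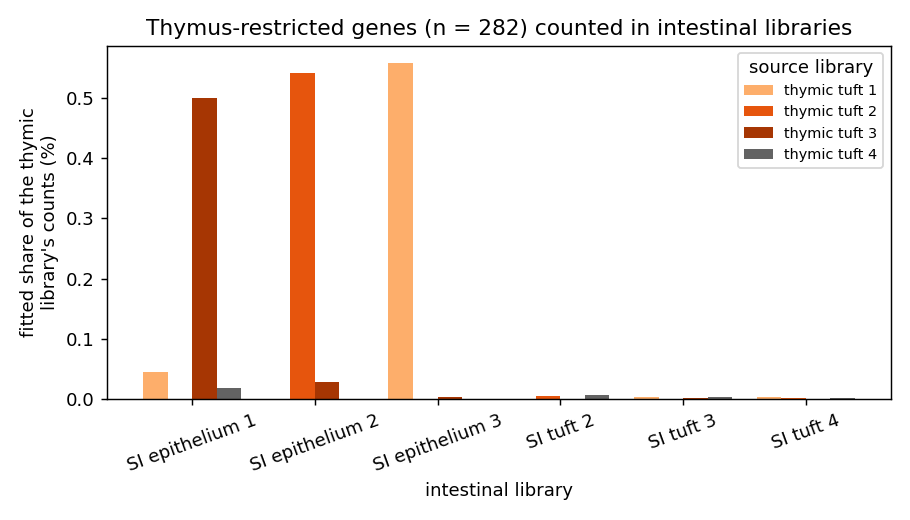
Share of each thymic tuft library's counts (%, bars by source library) found by fitting 282 thymus-restricted genes in each intestinal library. SI epithelium libraries 1, 2 and 3 follow thymic libraries 3, 2 and 1 at 0.501% to 0.559%, and SI tuft libraries, on which the genes were selected, reach 0.00712% at most.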

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

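The library that lay furthest from the rest of its group was sought in each value by Dixon's test, the gap to the next library divided by the range. This was done for 97 values (named genes, gene lists and measures of depth) over the thymic tuft libraries, the group with 4 replicates. Chance alone gives about 1 in 20, or 4.85 of 97, and 5 values passed. The number that passed is near what chance gives for independent values, but these values are not independent, since lists and named genes share members. It does not show that each value passed by chance.

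Thymic library 4 was the lowest for 3 lists of intestinal epithelium, measured as mean log2 CPM of the members. Enterocyte markers had a gap of 0.939 of the range (2.51 against 3.70 to 3.78), goblet cell markers 0.926 (3.36 against 5.48 to 5.65) and Paneth cell markers 0.872 (-0.17 against 2.61 to 3.01). After subtraction of the shares fitted for libraries 1 to 3, a step chosen after seeing the data, the largest gaps were 0.640, 0.634 and 0.532 of the range. They then belonged to another library or side: library 1 was the lowest for enterocyte markers, library 4 the highest for goblet cell markers and library 1 the highest for Paneth cell markers.

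Thymic library 1 was the highest for myeloid and dendritic cell markers, with a gap of 0.934 of the range (2.10 against 1.33 to 1.38). Ltc4s was the lowest in the same library, with a gap of 0.830 of the range (14.4 CPM against 28.8 to 31.8 CPM). No library was removed for these values.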

How the results depend on the processing

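Of 189 gene counts under alternatives, 180 stayed within 1.5-fold and 9 moved. With at least 10 CPM in 3 libraries, so that fewer genes were tested, 3289 genes were higher in thymic than SI tuft cells and 3536 higher than in SI epithelium. With only SI tuft and SI epithelium in the fit, 3475 genes were higher and 3513 lower in SI tuft cells. That fit took its spread from these groups alone, at 0.262 in SI epithelium and 0.489 in SI tuft cells, against 0.613 over all groups. How far this accounts for the larger counts was not tested. DESeq2's Wald test gave 584 SI tuft genes higher in thymic tuft cells; the cause was not tested. A minimum change of 2-fold left 702 SI tuft genes lower and 206 higher in thymic tuft cells, by construction. Genes lower in SI tuft cells than SI epithelium were 1426 without SI epithelium library 1 and 1432 without library 2, and at most 2754 without thymic library 4; the cause was not tested.

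Of 8221 results for genes under alternatives, 8025 stayed called or not called as before, 154 lost their call, 40 gained one and 2 turned direction. Of 1530 for lists, 1454 stayed as before, 45 lost their call, 28 gained one and 3 turned. All 5 turned when the partner library's share was subtracted, all in SI tuft against SI epithelium, and edgeR or camera then gave adjusted p = 0.0114 for Eya1 (range over alternatives 4.12e-05 to 0.0177) and 0.0299 for Tas2r138 (0.0299 to 0.984), and 0.424 for the medullary list (0.000525 to 0.424), 0.679 for MHC class II (0.0133 to 0.679) and 0.294 for thymic patterning factors (0.00402 to 0.294).

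Residual correlations gave no sign that libraries with the same replicate number share a mouse, but they cannot exclude it. Correlations of residuals over 8869 genes were -0.114 to 0.0628 for library pairs with the same number and -0.0699 to 0.0845 for other pairs. With the number as a replicate block, 1637 genes were higher and 1565 lower in SI tuft than SI epithelium, 4767 and 4172 in thymic against SI tuft cells, and 4889 and 4092 in thymic tuft against SI epithelium. With it the calls of Zg16 and Defa30 in SI tuft against SI epithelium ended (edgeR adjusted p = 0.0826 and 0.0734). The spread fitted for both genes includes the thymic libraries, of which library 4 was far lower than the others.

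DESeq2 size factors shifted the log2 fold changes by 0.242 in thymic against SI tuft cells and 0.229 in thymic tuft against SI epithelium, and upper quartile scaling shifted the former by 0.120. With DESeq2 size factors 6187 genes were higher and 3584 lower in thymic than SI tuft cells (63.3% against 55.2% of calls higher), and 6181 were higher and 3409 lower in thymic tuft than SI epithelium (64.5% against 56.2%). With 3 or 4 libraries per group and counts down to 38.7 × 1e6 per library, most 2-fold changes were missed in the simulations. Those simulations used a spread pooled over all groups, so recovery with each group's own spread was not tested.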

Other observations

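Families of genes with the same symbol stem were compared after the data were seen, over 181 families of at least 10 members. In thymic against SI tuft cells, 20 of 23 kallikrein genes (Klk), 10 of 10 Skint genes of epidermal and thymic epithelium, 10 of 10 Cxcl chemokine genes and 15 of 18 Serpinb protease inhibitor genes were higher. Cxcl10, a chemokine induced by interferon, was at 2.55 ± 3.20 CPM (n = 3) in SI tuft and 376 ± 86.6 CPM (n = 4) in thymic tuft cells (log2 fold change 7.19, SE 0.85, edgeR adjusted p = 2.2e-05). Cxcl1, a neutrophil attractant, was at 0.231 ± 0.109 and 129.6 ± 31.4 CPM (log2 fold change 9.11, SE 0.46, edgeR adjusted p = 2.58e-08). Collagen genes (Col) were higher in 25 of 37 cases and cilium genes of the Cfap stem in 16 of 26, and 11 of 13 fibroblast and endothelium markers, which include collagen genes, were higher as well, whereas 9 of 13 Ugt detoxification genes and 28 of 47 mitochondrial ribosomal genes (Mrpl) were lower. In SI tuft against SI epithelium 10 of 16 Galnt genes for mucin glycosylation were lower. No family was called by camera with an estimated correlation, with adjusted p = 0.104 for Klk, 0.226 for Cxcl, Skint and Ugt, 0.151 for Serpinb, Col and Cfap, 0.311 for Mrpl and 0.306 for Galnt. Cxcl10 overlaps the gene Art3, and reads of near-identical Klk genes are not separated with certainty.

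All tests of counts shared between libraries were chosen only after the result was seen. A single thymic library made up at least 88.8% of the fitted share in each SI epithelium library, with libraries 3, 2 and 1 in SI epithelium 1, 2 and 3. The remaining 11.2% at most was left to other thymic libraries. Expression by intestinal epithelial cells would not follow 1 thymic library, which argues against it as the main source for these genes as a set. The fit held no term for such expression, so it was not excluded for single genes. Carry-over of cells before amplification would need up to 15.7% of the sorted thymic cells if RNA per cell were equal. The reverse shares of the same pairs differed by a factor of 1.12 at most and those of 5 other pairings by 1.18 to 2.47. Mixing of the counts between paired libraries is in line with these tests, and carry-over was not told apart from misread index sequences.

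For the low tuft cell markers of thymic tuft cells, the tests of dilution and of scaling were chosen only after the result was seen, and the test of gene length, GC content and level was set before. Dilution by cells without these markers would lower all of them alike if the tuft cells of both organs were the same. Instead 74.4% of them (29 of 39) lay more than 2 SE from the median, from -5.96 for Siglecf to 6.29 for Gnb3. The median of -1.43 lay at percentile 0.38 of 10000 random lists matched for length, GC content and level, whose median was -0.65 with 95% between -1.18 and -0.23. With the scaling that moved it most the median was -1.19. Dilution alone would therefore not give this spread of the markers. Differences between the tuft cells of both organs spread the markers whether or not dilution lowers their median, so a part played by dilution stays open. A difference between the organs, their dissociation or the cell number is not separated by these tests.

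For enterocyte transcripts in SI tuft cells, the test of whole epithelium in the tuft cell gate was chosen only after the result was seen, and the test of a common source was set before. Cells or RNA of the whole epithelium would keep all lineage markers alike, but the median change of enterocyte markers lay at least 4.66 log2 units above that of goblet, Paneth and enteroendocrine markers. Only 8.70% of the enterocyte markers (2 of 23) lay more than 2 SE from their common change. A common source of enterocyte RNA or cells in both SI groups is therefore consistent with this test and stays open, as does expression by tuft cells.

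The regrouping of libraries was set before the data were examined. Between SI tuft and SI epithelium the real grouping gave 6988 genes in the fit of these groups alone and the highest other grouping 0, but 1 of 10 groupings is too few to exclude chance. The real grouping was 1 of 35 for thymic against SI tuft cells (8458 genes, highest other 0). It was also 1 of 35 for thymic tuft against SI epithelium (9354 genes, highest other 0). Mixed groupings add the difference between groups to the spread within them, so 0 calls there do not exclude chance for single genes.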
